A study of Mus musculus with 6 samples.

How the data were processed

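Gene expression was measured by RNA sequencing in 6 samples of naive CD4 T cells sorted from spleen and peripheral lymph nodes of male mice. The sort kept cells with CD4 and without CD25 or CD44 on the surface, among other criteria, which leaves resting T cells that have not met antigen. The labels describe every mouse as lacking Gulo, the enzyme of the last step of ascorbate (vitamin C) synthesis, so that ascorbate has to come from the drinking water. They give 3 samples from mice on ascorbate water and 3 from mice after its withdrawal. Nothing in the labels says that the replicates of a group came from separate mice, so p-values measure the spread between these samples, which may be in part technical.

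The table of values does not use the labels' names. Its 6 columns are named WT 1 to 3 and KO 1 to 3 for Gulo, whereas the labels describe no wild type, and no column name matches a sample title. The columns named WT were read as the ascorbate group and those named KO as the withdrawal group, because an animal with Gulo makes ascorbate and an animal without it does not. This reading is an inference from the names alone: no label states it, nothing else supports it, and it was not checked with the submitters. No value depends on it, since the columns were compared by their names. The columns could also be wild-type and knockout mice, or stand the other way round. For this reason the libraries are called named WT and named KO throughout, every difference is given as named KO minus named WT, and no difference can be taken as an established effect of ascorbate withdrawal.

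Libraries of polyadenylated RNA were made with the TruSeq Stranded mRNA kit, per the labels' protocols. STAR, RSEM and the mouse genome mm10 are listed per the submitters' processing notes, which give no versions here. The authors deposited estimated counts per gene, not normalized, for 55573 genes and 92 rows of ERCC spike-in controls. Of the deposited expected counts 6.40% were not whole numbers. All ERCC rows were at 0 in every library and were left out, and 0 rows named no gene. Whether strand was used in counting is not given in the sources used here, so genes overlapped on the other strand are uncertain. Of the gene identifiers, 55180 matched GENCODE M21 (mm10) with their version and 55480 without it, and coordinates come from that annotation.

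Total estimated counts were 51219508, 48371898 and 38464570 in WT 1, WT 2 and WT 3, and 37745677, 31156272 and 34909903 in KO 1, KO 2 and KO 3. The libraries named WT were thus deeper, and 1 count was worth 0.0195 to 0.0321 CPM, the usual unit of counts scaled to a common library total. Counts were rounded to whole numbers. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 14135, and libraries were scaled by TMM. The comparison was fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test with robust dispersions, no covariate). Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes under 0.05 are called. CPM values are TMM-scaled and given as mean ± SD, and fold changes are on the log2 scale with their standard error (SE). Symbols carried by more than 1 identifier were kept apart by identifier.

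The 36 gene lists were fixed before the data were examined, and the 33 with at least 5 tested genes were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The rule for named genes was fixed then too. It takes, in each direction, the 12 called genes of largest fold change whose libraries did not overlap and whose mean was at least 1 CPM, without receptor segments, predicted genes and pseudogenes. It adds up to 3 members of smallest p from each list, and a fixed set with Tet1, Tet2, Tet3, Gulo, Slc23a2, Cd4, Cd44, Cd5, Nr4a1, Foxp3, Il2ra and Cd8a. It named 133 genes, some of which are not reported here.

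The fit was tested on simulated data: 10 tables drawn from the means, spread and library sizes of the real libraries, each with 200 changed genes among 13938 run. It recovered 23.2% of genes changed 1.25-fold, 57.4% at 1.5-fold, 77.3% at 2-fold and 94.8% at 4-fold. On average 9.57% of its calls were unchanged genes, from 4.43% to 15.4% by table, which is above the nominal 5%. The limit set for this test was widened, and single tables replaced by their average, after the first simulated table had exceeded it. Among unchanged genes 4.66% had an unadjusted p under 0.05. A list shifted by 1.15-fold was called in 10 of 10 tables and 0.1 unchanged lists were called per table, with genes drawn independently of each other.

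Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom, no count filter, a mean of at least 5 CPM, the replicate number as a block, no receptor segments, no robust dispersions, a test against a fold of 1.2, other thresholds, an estimated correlation or fry for the lists, and each library left out in turn. Offsets for GC content and transcript length, and thinning to 1 depth, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.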

Results

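The data are estimated counts per gene in 6 libraries of sorted naive CD4 T cells, 3 named WT and 3 named KO in the table, at totals of 31156272 to 51219508 counts. By the labels the study asks how naive T cells respond in mice that cannot make ascorbate when it is withdrawn. Named WT was read as supplied with ascorbate and named KO as withdrawn, which is an inference from the column names that no label states. The labels also describe all 6 samples as Gulo-deficient, so the name WT goes against them.

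Gulo itself (chromosome 14, 65986786 to 66009207, mm10) was low in all libraries. Its estimated counts were 100, 29 and 109 in WT 1 to 3 and 21, 38 and 16 in KO 1 to 3, so that WT 2 lay below KO 2. The log2 fold change was -1.30 (SE 0.62, adjusted p = 0.278 by edgeR's quasi-likelihood test), which did not pass the threshold. Counts over the whole gene do not show whether a part of it is deleted, so they neither check the names nor the genotype. Replicates of either set differed by more than sampling noise, with a chi-square per degree of freedom of 9.34 or more for every pair. The first principal component held 37.2% of the variance and separated the sets, and KO 1 stood apart from the other 5 libraries with a score of 38.3 against 15.2 in KO 3 and 3.64 in KO 2.

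**Figure D1:**
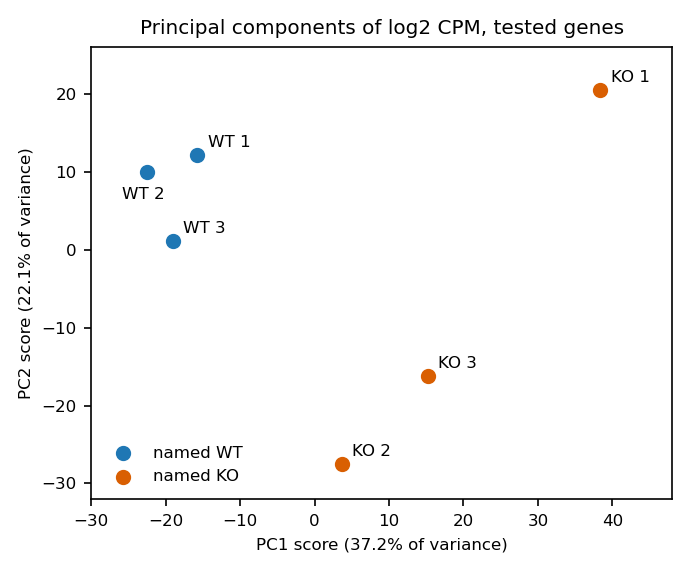
Scores of the 6 libraries on the first 2 principal components of log2 CPM over the 14135 tested genes, with blue points for libraries named WT and orange points for those named KO. The 3 libraries named WT have PC1 scores from -22.4 to -15.7, and the 3 named KO from 3.64 to 38.3. The names are the table's and their link to ascorbate is not established.

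Between the sets 352 of 14135 genes were called, 155 higher and 197 lower in the libraries named KO. Changes were mostly small: the median absolute log2 fold change of called genes was 0.44, and 55 exceeded 2-fold, 26 higher and 29 lower. Protein-coding genes made up 90.6% of the calls. At an unadjusted p under 0.05 there were 1541 higher and 1585 lower genes. In all 352 called genes the 3 libraries of one set lay above the 3 of the other. This held for 28.0% of all tested genes, where chance gives 10%. In simulated tables of this design 9.57% of calls were unchanged genes, above the nominal 5%. The number of calls depended on which library was left out. Without WT 1, WT 2 or WT 3 edgeR called 4, 0 and 12 genes higher and 14, 7 and 36 lower, without KO 3 it called 18 and 26, without KO 1 it called 117 and 195, and without KO 2 it called 608 and 647. Where 0 were higher, without WT 2, 1003 genes were higher at an unadjusted p under 0.05.

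The called gene with the largest increase among those named was Shisa7, at 0.756 ± 0.0398 CPM (SD, n = 3) in the libraries named WT and 3.28 ± 1.90 in those named KO, a log2 fold change of 2.12 (SE 0.43, adjusted p = 0.0467). Cercam (1.77), Zfp608 (1.46), Setbp1 (1.45), Pabpc1l (1.43), Insl3 (1.34) and Maneal (1.18) also rose, as log2 fold changes, from low levels of 0.536 to 2.65 CPM. Unc13a rose from 1.10 ± 0.139 to 2.43 ± 0.481 CPM. Itgad, an integrin alpha chain of leukocytes, had a log2 fold change of 1.42 (SE 0.24) from 2.99 ± 0.368 CPM. It stood at 11.3, 6.65 and 6.02 CPM in KO 1 to 3. The macrophage genes C1qa (9.05, 5.86 and 5.42) and C1qb (11.5, 6.90 and 6.68) also stood highest in KO 1, though these did not pass. Itgam, another myeloid gene, went the other way without passing, from 5.60 ± 0.796 to 3.63 ± 0.565 CPM (log2 fold change -0.63, adjusted p = 0.0708). Ccdc102a had a log2 fold change of 1.42 (SE 0.21) from 2.29 ± 0.609 CPM. Rundc3a rose from 4.32 ± 0.563 to 9.97 ± 2.34 CPM. Cd160, a receptor of the immunoglobulin superfamily found on T and NK cells, rose from 1.56 ± 0.386 to 3.40 ± 0.180 CPM. Without WT 2 none of these 12 kept an adjusted p under 0.05, and for Shisa7 it ranged from 0.00331 to 0.227 as single libraries were left out, at log2 fold changes of 1.63 to 2.48.

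Traf1 (chromosome 2, 34941750 to 34961772), an adaptor of TNF receptor signalling, was the most abundant gene among the 12 largest decreases. It fell from 77.7 ± 8.42 to 22.9 ± 4.99 CPM (n = 3 each), a log2 fold change of -1.77 (SE 0.17, adjusted p = 0.0184). Ctif, which acts in translation at the nuclear cap-binding complex, had a log2 fold change of -1.83 (SE 0.24), and Igf2bp2, an RNA-binding protein, one of -1.73 (SE 0.23). The histone genes Hist1h2bc (-1.70) and Hist1h4i (-1.25) fell too, both from families of near-identical copies whose reads are uncertain. Ldhd, a mitochondrial D-lactate dehydrogenase, fell from 5.73 ± 0.646 to 2.24 ± 0.588 CPM. Tmc3 (-1.31), Cd200r3 (-1.23), Galnt9 (-1.22), Actn2 (-1.21) and the long noncoding AC140469.1 (-1.34) fell from levels of 1.98 to 5.90 CPM. One of 2 overlapping entries for Ptp4a1, ENSMUSG00000026064.16, had -1.25 and is uncertain, since its reads are shared. When single libraries were left out, the adjusted p of Traf1 ranged from 0.00153 to 0.0993 and passed the threshold in 3 of the 6 fits, at log2 fold changes of -1.95 to -1.64.

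**Figure D2:**
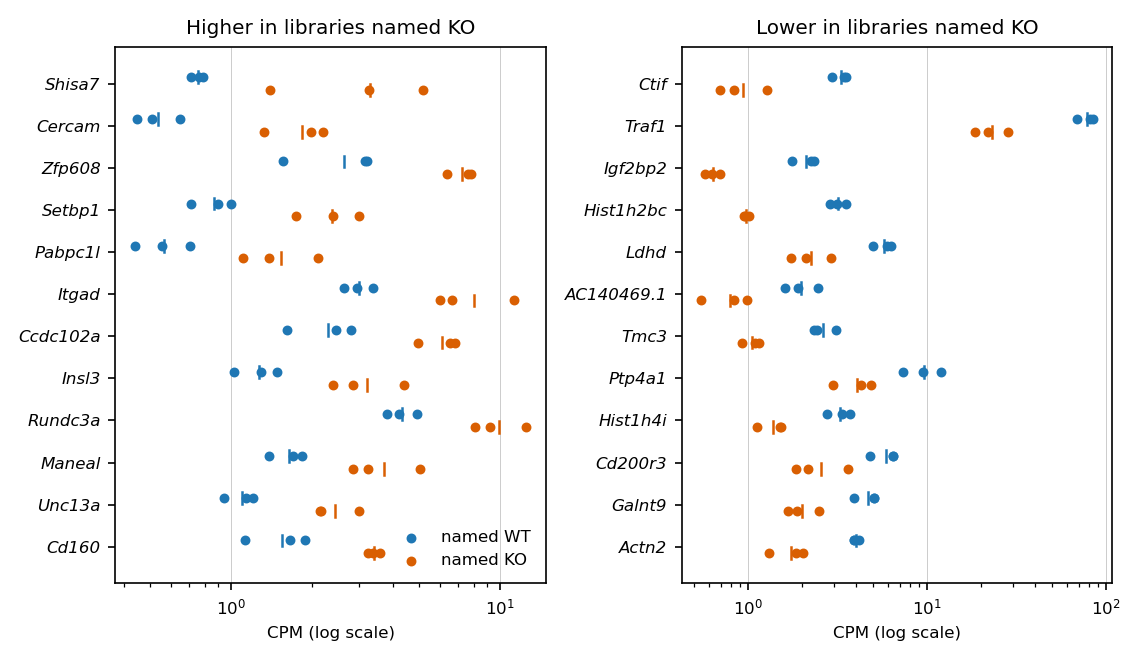
TMM-scaled CPM (log axis) of the 12 called genes with the largest increase and the 12 with the largest decrease under the fixed rule, with 1 point per library (blue, named WT; orange, named KO) and a short line at the mean of the 3. For each gene the points of one set lie above those of the other, as the rule requires, and Traf1 is the most abundant, at 77.7 against 22.9 CPM on average. Whether either set had ascorbate withdrawn is not known from the names.

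Among enzymes that use ascorbate, Tet1 (chromosome 10, 62804570 to 62908996), an oxidase of methylated cytosine, fell from 59.8 ± 5.12 to 42.8 ± 5.03 CPM, a log2 fold change of -0.48 (SE 0.09, adjusted p = 0.0362). Tet2 was at 64.0 ± 1.46 and 64.8 ± 7.18 CPM and Tet3 at 378 ± 36.1 and 427 ± 59.5 CPM, with log2 fold changes of 0.02 and 0.18 that did not pass (adjusted p = 0.914 and 0.389). Of 17 tested genes of the DNA methylation machinery 2 fell, Tet1 and Zbtb38, a reader of methylated DNA at -0.44, and 0 rose, the same 2 as when adjusted over the list alone. Mbd3 had -0.22 (adjusted p = 0.136). The adjusted p of Tet1 ranged from 0.0352 to 0.148 as single libraries were left out, at log2 fold changes of -0.58 to -0.43. Of 20 JmjC histone demethylases 0 were called by edgeR, with 4 higher and 4 lower at an unadjusted p under 0.05. Kdm3a at 0.25 and Riox2 at -0.27 passed when adjusted over the list alone. Kdm5a was at 0.22. Of 12 tested genes of ascorbate transport and recycling 0 were called, and 3 passed when adjusted over the list alone, Cyb5r3 (0.25), Gsto1 (0.65) and Slc2a3 (0.21). The ascorbate transporter gene Slc23a2 was at 72.7 ± 2.32 and 70.4 ± 0.512 CPM. Of 23 HIF hydroxylases and HIF targets 1 was called, P4ha2, a subunit of the collagen prolyl hydroxylase, which fell from 5.70 ± 0.420 to 3.08 ± 0.868 CPM, and 1 higher and 1 lower passed when adjusted over the list alone. None of these 4 lists passed camera (adjusted p = 0.583, 0.743, 0.454 and 0.903).

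Genes of naive T cell identity were abundant, at a median of 535 CPM in the libraries named WT and 486 in those named KO. Of the markers of the sort, Cd4 was at 979 ± 18.4 and 878 ± 25.4 CPM (log2 fold change -0.16, adjusted p = 0.123). Cd44, against which the cells were sorted, was at 34.2 ± 1.17 and 44.5 ± 8.19 (0.38, adjusted p = 0.116). Of 22 genes of naive T cell identity 3 fell and 0 rose: Lef1 and Foxo1, transcription factors of resting T cells, each by 0.34 on the log2 scale, and Il6st, the shared receptor chain of the IL-6 family, by 0.27. Adjusted over the list alone 2 were higher and 6 lower, and the list did not pass camera (adjusted p = 0.320).

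Of 26 genes induced by the T cell receptor 1 rose and 2 fell. Dusp6, a phosphatase of ERK, fell from 32.4 ± 2.35 to 18.5 ± 3.09 CPM (log2 fold change -0.81, SE 0.12, adjusted p = 0.0207), and Cd5, a receptor that dampens T cell receptor signals, from 466 ± 27.8 to 362 ± 28.9. Il2ra, the alpha chain of the IL-2 receptor (CD25, against which the cells were sorted), rose from 5.61 ± 0.891 to 10.2 ± 1.96 CPM (0.87, SE 0.16, adjusted p = 0.0313). Nr4a1 was at 81.9 ± 7.07 and 64.7 ± 10.5 CPM (adjusted p = 0.163). Adjusted over the list alone 2 were higher and 6 lower, and camera did not pass (adjusted p = 0.144). Of 27 genes of anergy and inhibitory receptors Cd160 rose, and Cd5, Cd6 (-0.37) and Izumo1r, the folate receptor of anergic and regulatory T cells (-0.47), fell (camera adjusted p = 0.980). When adjusted over the list alone, 4 were higher and 3 lower. Of 16 genes of regulatory T cells Il2ra rose and Izumo1r fell. Foxp3, their defining transcription factor, was at 9.81 ± 1.78 and 13.4 ± 1.63 CPM (0.46, adjusted p = 0.107) and Gpr83 at 0.67. Adjusted over the list alone 5 were higher and 1 lower, and the list did not pass camera (adjusted p = 0.115). Without WT 2, Cd5, Il2ra, Cd6, Izumo1r, Dusp6, Lef1, Foxo1 and Il6st did not pass. Across the 6 fits with a library left out, adjusted p ranged from 0.00918 to 0.169 for Cd5, from 0.00673 to 0.164 for Il2ra and from 0.00706 to 0.117 for Dusp6, while their log2 fold changes ranged from -0.43 to -0.32, 0.75 to 1.02 and -0.91 to -0.68.

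Lists of other T cell states held 0 called genes by edgeR. They were effector and memory T cells (27 tested, camera adjusted p = 0.266; 7 higher and 2 lower at an unadjusted p under 0.05), T helper 1 (12, 0.472; 2 and 2), T helper 2 (8, 0.237; 0 and 3), T helper 17 (7, 0.743; 1 and 0) and follicular helper T cells (11, 0.838; 3 and 2). Adjusted over the list alone 1 follicular helper gene was higher, and 0 passed in the other 4 lists.

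Of the 33 lists tested 6 passed camera at its preset correlation between genes, 5 lower and 1 higher in the libraries named KO, and 0 passed with an estimated correlation (adjusted p = 0.963). Genes of cholesterol synthesis were lower, with 21 of 24 below 0 and a median log2 fold change of -0.20 (adjusted p = 0.00112), which was -0.12 without KO 1 (adjusted p = 0.00260). Of them 2 fell and 0 rose. Hmgcs1, an early enzyme of the pathway, fell from 53.6 ± 0.612 to 44.2 ± 2.35 CPM, while Cyp51 at -0.41 did not pass (adjusted p = 0.0547). Adjusted over the list alone 9 were lower and 1 was higher. AP-1 immediate early genes were lower, with 17 of 19 below 0 and a median of -0.21 (adjusted p = 0.00509), and 5 lower and 1 higher adjusted over the list alone. Their 1 called member went the other way: Socs3, an inhibitor of cytokine signalling, rose from 183 ± 19.2 to 275 ± 36.1 CPM. Klf6 at -0.52 and Ppp1r15a at -0.69 did not pass (adjusted p = 0.0516 and 0.0670). With an estimated correlation between genes, neither list passed (adjusted p = 0.963 for each).

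Genes of the unfolded protein and integrated stress responses were lower, with 19 of 23 below 0 and a median of -0.17 (adjusted p = 0.00509). Hspa5 and Calr, chaperones of the endoplasmic reticulum, fell from 341 ± 28.0 to 239 ± 23.0 CPM and from 369 ± 14.9 to 281 ± 34.1, and Hsp90b1 was at -0.45 (adjusted p = 0.0753). Over the list alone 7 were lower and 1 higher. Heat shock genes were lower by their median of -0.22, with 12 of 14 below 0 (adjusted p = 0.0210), though their mean was -0.05 because Hspa1b stood at 2.06 from 0.479 ± 0.125 CPM without passing. Chordc1, a partner of HSP90, fell by 0.29 on the log2 scale and 5 genes were lower over the list alone. Hspa4l (-0.25) and Hsf1 (-0.18) were not called over all genes. Nuclear-encoded subunits of oxidative phosphorylation were lower by a median of -0.07, with 61 of 77 below 0 (adjusted p = 0.00509). Of them edgeR called 0, and 10 were lower and 0 higher at an unadjusted p under 0.05. Without KO 1 these 3 lists did not pass (adjusted p = 0.0693, 0.176 and 0.362), with 1 library fewer and medians of -0.12, -0.16 and -0.02. Summed unfolded protein response genes were still lower in KO 2 and KO 3, at 1922 and 1942 CPM, than in the libraries named WT, at 2156 to 2352, and so were heat shock genes, at 2928 and 3254 against 3321 to 4011. Oxidative phosphorylation genes were not, since KO 2 at 6023 CPM lay above WT 1 at 5980. With an estimated correlation none of the 3 passed (adjusted p = 0.963 for each).

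STAT5 cytokine targets were higher, with 12 of 16 above 0 and a median log2 fold change of 0.30 (adjusted p = 0.00509). Il2ra and Socs3 rose, and Cish, a STAT5-induced inhibitor, was at 14.2 ± 1.89 and 32.4 ± 9.43 CPM (1.19, adjusted p = 0.0708). Over the list alone 6 were higher and 0 lower. Without KO 3 the list did not pass (adjusted p = 0.0969, median 0.25), nor did it with an estimated correlation (adjusted p = 0.963). With that correlation 0 of the 33 lists passed at an adjusted or unadjusted p under 0.05, and fry, which asks whether the genes of a list move one way without comparing them with other genes, passed 0 at an adjusted p under 0.05 and 5 at an unadjusted one.

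**Figure D3:**
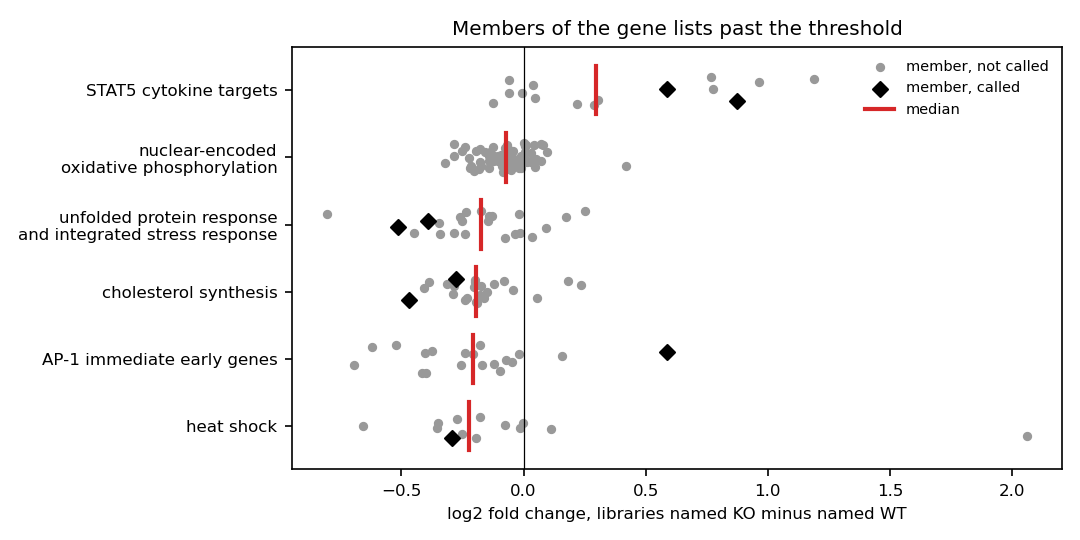
Log2 fold changes (named KO minus named WT) of the tested members of the 6 lists past the threshold, with gray points for members not called, black diamonds for called members and a red line at the median. Medians run from -0.22 for heat shock genes to 0.30 for STAT5 cytokine targets, and most members lie within 1 log2 unit of 0. The points are spread vertically at random, and the link of the names to ascorbate is not established.

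The other lists of cell function did not pass. Of 18 p53 targets Trp53inp1 fell by 0.34 on the log2 scale (camera adjusted p = 0.992) and 3 were lower over the list alone. No gene was called by edgeR in glycolysis (18 tested, camera adjusted p = 0.935), cell cycle (35, 0.903), oxidative stress through NRF2 (24, 0.271), the type I interferon response (42, 0.114), the interferon gamma response and antigen processing (27, 0.454), the glucocorticoid response (19, 0.319), mitochondrial genome transcripts (13, 0.980) or cytosolic ribosomal proteins (87, 0.903). At an unadjusted p under 0.05 these 8 lists held, in the same order, 2, 3, 2, 0, 1, 3, 0 and 0 higher genes and 1, 3, 3, 5, 1, 1, 1 and 0 lower ones. Over the list alone 2 glucocorticoid response genes were higher, Il7r (0.52) and Fkbp5 (0.75), and Btg1 (-0.22) was lower, while the other 7 lists held 0.

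Markers of cells outside the sort were measured as well. Cd8b1 (chromosome 6, 71322788 to 71337494), the CD8 beta chain, fell from 17.1 ± 1.30 to 7.45 ± 0.667 CPM (log2 fold change -1.20, SE 0.10, adjusted p = 0.00147) and stayed called whichever library was left out. Cd8a, the CD8 alpha chain, was at 0.688 ± 0.0884 and 0.316 ± 0.290 CPM (adjusted p = 0.257). Of 21 B cell genes Ighm fell from 487 ± 45.6 to 379 ± 25.5 CPM and 17 were below 0, with 1 lower adjusted over the list alone (camera adjusted p = 0.419). Of 14 genes of NK and innate-like T cells Prf1, perforin, fell from 32.4 ± 3.38 to 22.9 ± 1.89 CPM, and 2 were lower adjusted over the list alone (camera adjusted p = 0.266). No gene was called by edgeR among 20 myeloid genes (0.454), 7 dendritic cell genes (0.715) or 9 erythroid genes (0.547), with 4 higher and 2 lower at an unadjusted p under 0.05 in the first and 0 in the others. Of the myeloid genes 1 was higher and 1 lower when adjusted over the list alone. C1qa and C1qb were at 0.84 and 0.92 on the log2 scale (adjusted p = 0.105 and 0.0630), and Itgam at -0.63 (adjusted p = 0.0708). Summed erythroid genes varied within sets, from 391 to 815 CPM in the libraries named WT and from 45.3 to 766 in those named KO. Summed dendritic cell genes were 63.8 to 67.8 CPM in the libraries named WT and 49.9 to 55.4 in those named KO. Summed genes of NK and innate-like T cells were 64.6 to 69.6 and 51.6 to 54.7. Single genes weighed heavily in these sums. They were Prf1 in the second and, in the first, Bst2, at 44.4 ± 4.56 and 34.3 ± 6.98 CPM without passing. By gene, 3 dendritic genes lay above 0 and 4 below (median log2 fold change -0.03). Those of NK and innate-like T cells split 7 and 7 (median -0.04), but 0 were higher and 4 lower at an unadjusted p under 0.05 by edgeR. Among these 4, Gzma was at 1.23 ± 0.619 and 0.420 ± 0.111 CPM and Eomes at 4.17 ± 0.643 and 2.78 ± 0.624. Neither passed over all genes (adjusted p = 0.0756 and 0.130 by edgeR). Of the platelet and the stromal lists 4 genes each were tested, too few for the list test, and 0 were called, with 0 higher and 1 and 0 lower at an unadjusted p under 0.05. Without WT 2, Ighm and Prf1 did not pass.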

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

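Offsets for GC content and length and thinning to 1 depth were chosen after seeing the data; the other settings were fixed before. Calls of higher and lower genes stayed within 1.5 times of 155 and 197 with RLE or upper-quartile scaling, limma-voom, a mean of at least 5 CPM, no receptor segments, no robust dispersions and thinning, and scaling moved the median fold change of all genes by at most 0.00461 on the log2 scale. Other settings moved the counts further: DESeq2 called 498 higher and 547 lower, no count filter 373 and 497, a threshold of 0.10 gave 522 and 546, one of 0.01 gave 1 and 9, a test against a fold of 1.2 gave 3 and 17, and offsets for GC content and length gave 249 higher. DESeq2 gave no adjusted p for 3 of the higher and 1 of the lower genes. By construction a stricter threshold and a fold bound lower the counts, and a looser threshold raises them. The cause of the other shifts was not tested. With single libraries left out, higher calls ranged from 0 (without WT 2, with 1003 higher at an unadjusted p under 0.05 by edgeR) to 608 (without KO 2), lower calls from 7 to 647 and lists from 6 to 9. Of the called genes 0 higher and 6 lower passed in all 6 such fits. Of the 6 lists 0 passed with an estimated correlation and 0 with fry.

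Of the 45 named genes called, RLE scaling, DESeq2 and the block kept 45 each and limma-voom 44. Leaving out WT 1, WT 2, WT 3, KO 1, KO 2 or KO 3 kept 3, 1, 12, 32, 44 and 7, fewer samples being part of the loss. No named gene that was called changed direction in any of these settings. The libraries of the 2 sets did not overlap in any called gene, so leaving 1 out could hardly reverse a direction. Of 880 values of uncalled named genes 7 changed sign. The replicate number as a block gave 396 higher, 479 lower and 8 lists, but the numbers are not said to pair the samples. Deviations of same-numbered libraries correlated at 0.14, -0.03 and 0.03 across genes. KO 2 and KO 3 correlated better with another number than their own. Deviations from means of only 3 libraries are tied to each other, so these values cannot decide whether the samples were paired. At these depths a gene with 3 counts stood at 0.0586 to 0.0963 CPM, which bounds what counting can show for the lowest genes.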

Other observations

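The tests of Cd8b1 and of overlapping genes, and the choice of genes in these first 2 paragraphs, came after the values were seen, and the overlap test was replaced with another more than once; all directions are named KO minus named WT, and the link of these names to ascorbate is not established. Apart from Cd8b1, the genes called whichever library was left out included Igsf23 (40.8 ± 1.93 to 20.7 ± 1.44 CPM), Cers6, a ceramide synthase (54.5 ± 2.45 to 29.4 ± 3.29), Gabrr2 (14.1 ± 0.965 to 6.62 ± 1.01) and the linker histone gene Hist1h1c (30.2 ± 2.98 to 14.2 ± 0.979; SD, n = 3 throughout). These 4 were lower in the libraries named KO. Of 30 tested genes of the replication-dependent histone clusters 3 fell, 0 rose and 20 were below 0, with a median log2 fold change of -0.21. Their transcripts mostly lack poly(A) tails, so libraries of polyadenylated RNA hold a part of them only.

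KO 1 differed from the other 5 libraries in named functions. Its summed glucocorticoid response genes stood at 6456 CPM against 4343 to 4921 in the others, with Tsc22d3 at 683 CPM, Ddit4 at 376 and Cxcr4 at 134, where the other libraries held 233 to 328, 91.1 to 178 and 24.3 to 42.5. Its summed type I interferon genes stood at 2897 CPM against 3670 to 4380, and its summed unfolded protein response genes at 1644 against 1922 to 2352. Single genes of other cells stood apart in it too. Jchain of plasma cells was at 32.8 CPM against 1.66 to 5.57. The erythroid genes Car1, Slc4a1 and Ermap were at 10.3 against 0.443 to 1.70, 10.8 against 0 to 1.12 and 5.12 against 0.685 to 1.07. The full erythroid list did not stand apart, at a sum of 766 CPM in KO 1 and 815 in WT 1. Summed B cell genes, with Jchain among them, were at 593 CPM in both. Ighm made up most of these sums, at 389 CPM in KO 1 and 488 in WT 1. In the other libraries the sums were 397 to 580 CPM and Ighm 349 to 533. The rest of the B cell list thus stood higher in KO 1 than in any other library. With 1 such library no test applies. Rnu3a has 2 entries on chromosome 10 that start at 40258467 and end at 40258680 and 40258679. The first, ENSMUSG00000065870.2, had 17, 32 and 26 counts in WT 1 to 3 and 0 in each library named KO, and the second, ENSMUSG00000106147.1, had 0 in each library named WT and 20, 33 and 33 counts in KO 1 to 3. Both are among the 352 calls, at log2 fold changes of -7.50 and 8.07. There were 73 other same-strand pairs that share at least 80% of their span, in 27 groups, the largest of 45 pairs. In 0 of them did the mean share of reads on 1 entry differ by over 50 percentage points between the sets. The largest difference was 36.1 points, and the exact 95% interval for the groups reaches 12.8%. Pairs with nearly all reads on 1 entry could hardly pass this bound, so smaller shifts stay open.

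The first pattern is the 352 calls. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many, and the highest other gave 8, but 10 splits are too few for a share under 0.05. Every other split also mixes the 2 sets, so any difference between them adds to the spread within its groups and can lower its calls. With GC content and transcript length regressed out 95.5% of the called genes stayed called in their direction, and with all libraries thinned to 1 depth 91.8% did, which argues against either as the whole cause. Reads of overlapping genes assigned differently in the 2 sets, as for Rnu3a, stay open. Of 349 called genes with coordinates 57.3% overlapped another gene on either strand (exact 95% interval 51.9% to 62.6%), against 56.1% of tested genes. On the same strand 27.2% of called genes did, against 25.7% of tested genes. Whether strand was used in counting is not known. A difference in processing or batch that follows the sets, and the ascorbate state or genotype itself, stay open and cannot be told apart by this design.

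The second pattern concerns the name KO. If only the libraries named KO carried DNA of another strain around Gulo, called genes might gather there. Within 10 Mb of Gulo 2 of 129 tested genes were called, an odds ratio of 0.614 (exact 95% interval 0.0733 to 2.28, Fisher's exact test, two-sided p = 0.774). This interval lies below the 3-fold excess set beforehand, which argues against such an excess of calls. Within 20 Mb 3 of 358 were called, an odds ratio of 0.325 (interval 0.0664 to 0.966). Within 5 Mb 1 of 69 was called, and the interval, 0.0143 to 3.33, does not exclude the excess. A block that changes the expression of few genes would not show in these counts, so it stays open. Nor do they show that the 6 samples share a genotype, since a knockout made in the same strain would leave no such trace.

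The third pattern is Cd8b1, which was lower in all 3 libraries named KO. CD8 T cells in the sort would bring Cd8a with it, yet Cd8a reached at most 5% of the Cd8b1 count in the libraries named WT (3.79%, 3.41% and 5%). Such cells are therefore an unlikely source of most Cd8b1 reads. The ascorbate state, the genotype and other causes of the difference stay open, as untested.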
